A study of Mus musculus with 12 samples.

How the data were processed

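The data were transcript levels in the heart of C57Bl/6 mice, measured on Illumina bead arrays with biotin-labelled RNA made from total RNA with the Illumina TotalPrep kit, per the labels' protocols. The 12 arrays fell into 3 groups of 4: young mice, aged mice, and aged mice given spermidine in the drinking water. Each title gives its sample a number of its own, read here as an animal number; nothing else in the labels states that the samples are separate animals, so p-values measure the spread between these samples. Sex, time of collection, slide and scan date were not given in the sources used here.

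The submitters deposited 2 tables of 25697 probes on the same arrays, and the unit of both is linear intensity in whole numbers. The table used for the main values is called non-normalized, per its deposited name. Tested on its values, 24.1% lay below 0, so that a background had already been subtracted from each array. The other deposited table held intensity values that the submitters had normalized by a method not given in the sources used here. Its arrays all had a median intensity of 21, and it served as an alternative.

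The planned background correction of limma needs a detection p for each probe or control probes. The table used here held neither, so quantile normalization alone was applied to the background-subtracted intensities, 16 was added, and log2 was taken. A log2 difference on this scale understates the change of dim probes. A probe was kept if it lay above the 25th percentile of the array on at least 4 of the 12 arrays, which left 20573 probes (80.1%). A background limit was set on each array at 3 SDs of the values below 0 mirrored about 0. It lay between 13.2 and 15.8 intensity units, and 45.5% to 48.0% of the probes lay above it. Where a probe was above this limit on no array of the dimmer group, the ratio is given as "at least N-fold": the brighter group's mean against, per array of the dimmer group, the higher of the lowest signal among probes above the limit and the probe's own value. No fold is given where both groups lay below the limit. The number of arrays limits the precision of every value.

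Gene names came from the platform annotation, updated through a RefSeq gene table of the C57BL/6J reference assembly. Of the 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 were unnamed here. The Entrez ID matched 23962 and the accession 9 more, and 8 symbols changed. The kept probes named 13708 genes, and 1284 kept probes were unnamed. No coordinates are printed, since the tables used here name no genome build. For a gene list, each gene was represented by its probe with the highest mean.

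Each comparison was made with limma (lmFit and eBayes) in one model of the 3 group means over all 12 arrays, with 9 residual degrees of freedom, two-sided, and Benjamini-Hochberg adjusted p below 0.05 as the threshold over all kept probes. Every adjusted p of a probe below is from this limma fit. Of 41 gene lists that were fixed, along with the tests and the rule for named genes, before the data were examined, 40 had at least 5 measured members and were not reserved for a check of sex-linked genes. They covered energy metabolism, ribosomes, contraction, matrix, inflammation and immunity, stress responses, polyamines, autophagy, the clock, and markers of other cell types. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. A correlation estimated from each list's residuals and fry were alternatives. The p of fry tests whether a list's genes move, on balance, one way, and does not compare the list with other genes. The score of a list in an animal is the mean over its members of the log2 value minus that gene's mean over the 12 arrays. Scores were compared by a two-sided exact permutation test of 4 against 4 (70 arrangements, smallest possible p = 0.0286).

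The genes named are, per comparison, the 10 largest increases and the 10 largest decreases past the threshold with 1 probe per gene, or all of them if fewer passed. Where fewer than 5 passed, the 5 smallest p in each direction were added. Up to 4 members with the smallest p were named for each list described, along with a fixed panel of genes for natriuretic peptides, myosins, collagens, cell cycle inhibitors, cytokines, polyamine enzymes, autophagy and metabolism. Genes named outside this rule are marked as chosen after their values were seen. Of the panel, C3, Amd1, Sms, Bnip3 and Ddx3y were not analysed here.

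The comparison of aged with young hearts and that of spermidine-treated with aged hearts share the aged arrays, so relations between them were set beside 100 simulations built from the residuals of the arrays, and computed again with the aged arrays split into 2 pairs. The simulation was revised after its first result had been seen, because it made more ageing calls than the data did. The form reported still made 324 on average, against 164 in the data. The earlier form reached the observed share of probes toward young less often than the form reported.

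The limma step was tested on simulated data for the comparison of aged with young hearts, with 200 of 20573 probes changed in each of 10 simulations. It recovered 16.4% of changes of 0.5, 75.4% of changes of 1, 99.2% of changes of 2 and 99.4% of changes of 3 on the log2 scale, and 5.2% of its calls were false. The list test called 10 of 10 simulated lists moved by 0.3 and 0 of 10 unmoved lists. These simulations drew the noise of each probe independently, so the genes of a simulated list were uncorrelated. In the data the estimated correlation reached 0.63 for the antigen presentation list and 0.44 for the interferon list. The shares of false calls in the simulations therefore do not carry over to the data.

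The alternatives were the submitters' table, other normalizations and background treatments, other filters on dim probes, eBayes with trend and robust, array weights, only the 8 arrays compared, the mean over the probes of a gene, the replicate number as a block, a gene-wise Student test, and leaving out each array in turn. A background-limit filter, an offset of 64, and 2 settings that leave out arrays of unlike tissue make-up were added after seeing the data. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.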

Results

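Transcripts were measured in heart samples of C57Bl/6 mice on 12 arrays, read as 1 per animal from the numbers in the titles: 4 young mice of 6 months, 4 aged mice of 30 to 32 months, and 4 aged mice that had drunk 3 mM spermidine, a natural polyamine, from month 4. The series concerns protection of the heart and lifespan under spermidine. Its arrays answer which transcripts differed between young and aged hearts, and which differed with spermidine at old age. Mean intensity per array lay between 259 and 313, and 11689 to 12337 probes per array stood above the background limit. Arrays of a group correlated with each other across 8949 bright probes at r between 0.974 and 0.995 in young, 0.960 and 0.983 in aged, and 0.979 and 0.983 in spermidine-treated hearts. No pair of arrays was identical.

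Aged hearts held more transcript of the chemokine Ccl8 and of the antitrypsin genes Serpina1b and Serpina1d than young hearts, and less of the receptor components Ramp1 and Il6st. As lists, cytokine and chemokine, macrophage and complement genes were higher. With an estimated correlation the cytokine call passed (adjusted p = 0.00478), and the macrophage and complement calls were lost (0.0734 and 0.139). In fry these lists passed, with adjusted p of 7.27e-05, 0.00542 and 0.0200 in the same order. Ccl8, which attracts monocytes, stood at 8.26 ± 0.38 log2 intensity in aged and 5.07 ± 0.28 in young hearts (SD, n = 4 each), a 9.08-fold rise (log2 difference 3.18, SE 0.25, adjusted p = 0.000128). Ramp1, a co-receptor for the neuropeptide CGRP, fell by 1.67 on the log2 scale, from 7.96 ± 0.22 to 6.29 ± 0.53 (SE 0.24, adjusted p = 0.00596). Il6st, the shared signalling subunit of the Il6 receptor family, fell by 1.24 (SE 0.24, adjusted p = 0.0317). The call of Il6st passed in only 5 of 12 fits that left out 1 array, against 12 of 12 for Ramp1. Of 20573 probes, 164 passed the threshold, 111 higher and 53 lower in aged hearts, standing for 137 named genes and 16 unnamed probes.

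Among the other large increases were the kallikrein Klk1b26 (7.92 ± 0.76 against 4.93 ± 0.24, 7.91-fold, adjusted p = 0.000521), the potassium channel Kcnk1 (7.24 ± 0.32 against 4.51 ± 0.36, 6.64-fold, adjusted p = 0.000962) and Csprs (7.90 ± 0.45 against 5.85 ± 0.20, 4.13-fold, adjusted p = 0.000521). Klk1b26 and Csprs belong to families of similar genes, so their probes can catch related transcripts. The same holds for Serpina1b and Serpina1d, near-identical genes of the antitrypsin family. Serpina1b rose 5.36-fold (adjusted p = 0.000421), and Serpina1d rose at least 3.33-fold (adjusted p = 0.00124) from below the background limit on all 4 young arrays. Vgll2, a transcription cofactor of muscle, rose at least 2.59-fold (adjusted p = 0.00205), and the lectin Cd209b at least 2.05-fold (adjusted p = 0.00519), while its other probes, with log2 differences of 0.42 and 0.87, did not pass. Cap1, a regulator of actin, rose at least 8.21-fold (adjusted p = 0.0172). Its probe stood at 1 of 2 levels, 7.59 to 8.58 in aged and 3.56 to 4.61 in young hearts. In treated hearts it was at 3.89 to 4.09 in replicates 1 to 3 and at 7.55 in replicate 4. Whether this probe follows the whole level of the gene was not tested. The cytochrome Cyp2b10 rose 10.4-fold (adjusted p = 0.0199), with a log2 difference of -0.01 on its other probe. Klk1b26 lay above the background limit on 2 young arrays, Ccl8 on 3, and Kcnk1, Serpina1b and Cyp2b10 on 1, so their folds rest in part on values below the limit.

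Among the decreases, Ppp1r3b, which targets a protein phosphatase to glycogen, was at least 1.68-fold lower in aged hearts (log2 difference -1.12, SE 0.12, adjusted p = 0.00117). Ddc, the decarboxylase that makes dopamine and serotonin, fell by 1.17 (SE 0.20, adjusted p = 0.0204), and the sorting receptor Sorcs2 fell by 1.18 (adjusted p = 0.0141). Srpr, a subunit of the signal recognition particle receptor, fell from 8.99 ± 0.20 to 7.49 ± 0.69 (adjusted p = 0.0381), the cyclin Ccng2 fell by 1.31 (adjusted p = 0.0421), and Eps8l1 fell by 1.12 and Spata7 fell by 1.10 (adjusted p = 0.0448 each). In aged hearts Eps8l1 and Spata7 lay above the background limit on 1 array, Sorcs2 on 2 and Ccng2 on 3. Timm9, a chaperone of mitochondrial import, fell by 0.98 (adjusted p = 0.0381), although other probes of it differed by 0.07 and 0.65.

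**Figure D1:**
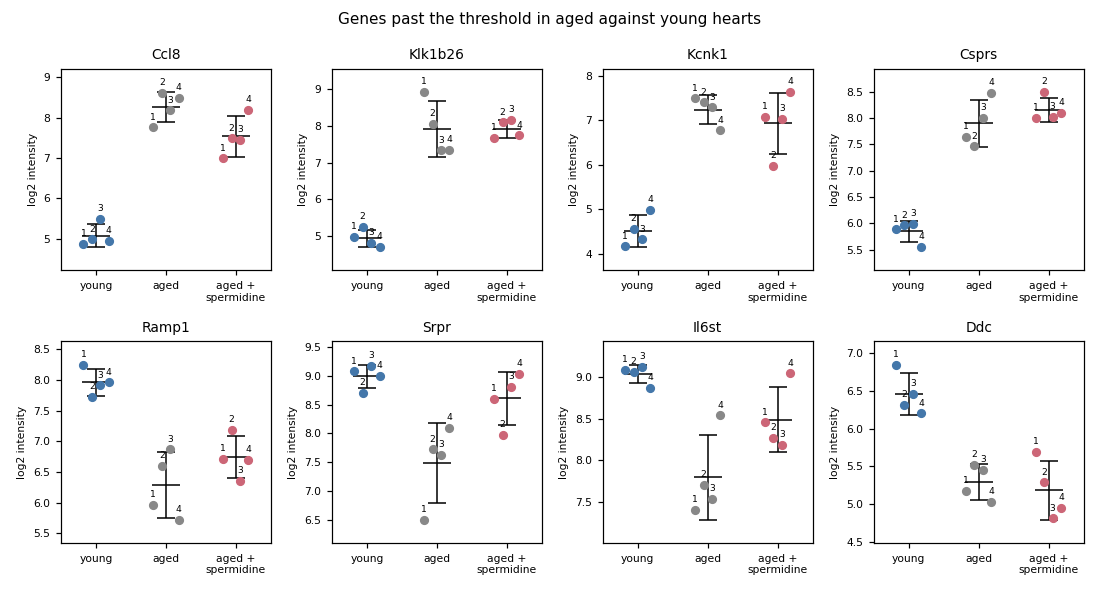
Log2 intensity (y axis) of 8 genes past the threshold in aged against young hearts, by group (x axis). Each point is 1 animal, numbered by replicate, the long dash is the group mean and the bars span 1 SD either side (n = 4). Ccl8 has means of 5.07 in young, 8.26 in aged and 7.53 in spermidine-treated hearts.

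The count of probes changed whichever array of the 2 groups was left out. A fit with fewer arrays also has less power, so a fall in the count does not by itself point to the array left out. It was 77 without aged replicate 1, 77 without aged replicate 2, 102 without aged replicate 3, 559 without aged replicate 4, and 41, 49, 42 and 75 without young replicates 1, 2, 3 and 4. Of the 20 genes named above, 10 passed in all 12 fits that each left out 1 array: Ccl8, Klk1b26, Kcnk1, Serpina1d, Serpina1b, Cd209b, Vgll2, Csprs, Ramp1 and Ppp1r3b. The calls of the other 10, Cap1, Cyp2b10, Srpr, Ccng2, Il6st, Sorcs2, Ddc, Eps8l1, Spata7 and Timm9, were lost in some of these fits. All 10 were lost without young replicate 1 (adjusted p 0.0546 to 0.148), 9 without young replicate 2 (0.0527 to 0.124), 9 without young replicate 3 (0.0529 to 0.132) and 6 without young replicate 4 (0.0579 to 0.109). Without aged replicates 1, 2 and 3, 5 (0.0539 to 0.106), 6 (0.0519 to 0.116) and 6 (0.0659 to 0.104) were lost. The spermidine arrays share the estimate of spread, and without their replicates 1 to 4 the losses were 3 (0.0510 to 0.0567), 2 (0.0524 to 0.0578), 4 (0.0501 to 0.0624) and 3 (0.0509 to 0.0587).

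Of the 40 gene lists, 8 passed in aged against young hearts, 5 upward and 3 downward. Of the 35 splits of the 8 arrays, 15 gave at least as many lists, so chance is not excluded for this count. Macrophage markers were higher in 22 of 25 measured members (median log2 difference 0.42, adjusted p = 1.41e-09; adjusted p = 0.0734 with an estimated correlation). Cd84, a receptor of leukocytes, rose (1.05, adjusted p = 0.0231), while F13a1 (0.72), Adgre1 (0.68) and Mrc1 (0.61) did not pass over all probes. The count was 1 over all probes and 11 adjusted over the list alone. Cytokines and chemokines were higher in 34 of 45 (median 0.22, adjusted p = 1.61e-06), and this call also passed with an estimated correlation (adjusted p = 0.00478). Ccl8, Ccl7 (0.79), Ccl12 (1.08) and Lcn2 (1.09), an iron-carrier binding protein of neutrophils, were the 4 that rose over all probes. Adjusted over the list alone, 12 rose and 1 fell. Complement genes were higher in 13 of 15 (median 0.29, 0.19 without aged replicate 4, adjusted p = 0.000692; adjusted p = 0.139 with an estimated correlation), with C4b (1.18) and C1qc (0.72) past over all probes, and 2 adjusted over the list alone. Of these members the call of Ccl8 passed in all 12 fits that left out 1 array. Those of Cd84, Ccl7, Ccl12, Lcn2, C4b and C1qc did not: 6 were lost without young replicate 1 (adjusted p 0.0588 to 0.148), 5 without young replicate 2 (0.0793 to 0.123), 5 without young replicate 3 (0.0649 to 0.126) and 5 without young replicate 4 (0.0579 to 0.108). Without aged replicates 1 to 4 it was 5 (0.0552 to 0.101), 3 (0.0560 to 0.103), 5 (0.0515 to 0.0921) and 1 (0.0506), and without spermidine replicates 1 to 4 it was 1 (0.0516), 2 (0.0524 to 0.0586), 2 (0.0510 to 0.0616) and 2 (0.0520 to 0.0540).

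Antigen presentation genes were higher in 19 of 21 (median 0.43, adjusted p = 8.77e-05; adjusted p = 0.846 with an estimated correlation), but 0 members passed in limma over all probes or adjusted over the list alone, and 8 had an unadjusted p below 0.05. Nlrc5, an activator of class I genes, differed by 1.26 and the peptide transporter Tap1 by 1.20. The median was 0.77 without aged replicate 1 and 0.24 without aged replicate 3, and the call passed in all 12 fits that left out 1 array. The list's score was 0.95 in aged replicate 3 and 0.77 in aged replicate 4 but -0.45 and -0.07 in aged replicates 1 and 2. Interferon-stimulated genes were higher in 26 of 38 (median 0.14, adjusted p = 0.018; adjusted p = 0.991 with an estimated correlation), with 0 members past in limma, 0 adjusted over the list alone and 9 at an unadjusted p below 0.05. Without aged replicate 4 the median was -0.04 (adjusted p = 0.784), without aged replicates 1 and 2 it was 0.24 and 0.27, without aged replicate 3 the adjusted p was 0.11, and without young replicate 4 it was 0.094.

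Immediate early genes were lower in 18 of 25 (median -0.27, adjusted p = 0.0102; adjusted p = 0.515 with an estimated correlation), with 0 past in limma over all probes, 7 lower adjusted over the list alone and 8 at an unadjusted p below 0.05. Fos (-1.04), Egr1 (-0.97), Dusp1 (-0.61) and Zfp36 (-0.47) had the smallest p. Without young replicate 3 the adjusted p was 0.091, and without young replicate 2 the median was -0.18. Cytosolic ribosome genes were lower in 45 of 56 (median -0.10, adjusted p = 0.00406; adjusted p = 0.846 with an estimated correlation), and without aged replicate 4 the adjusted p was 0.121. Smooth muscle and pericyte markers were lower in 13 of 17 (median -0.18, adjusted p = 0.018; adjusted p = 0.846 with an estimated correlation), with Pdgfrb, a receptor on pericytes, at -0.51. Without aged replicate 4 the median was -0.07 and the adjusted p was 0.278, and without young replicate 2 it was 0.2. In both of these lists 0 members passed in limma over all probes and 0 adjusted over the list alone, with 16 ribosome genes and 4 muscle and pericyte markers at an unadjusted p below 0.05. By score per animal, the macrophage, cytokine, complement, immediate early and clock lists differed at the smallest exact p that 4 against 4 allows (0.0286), and 0 of the 40 lists passed after adjustment. Time of collection was not given, and for the clock and immediate early lists it cannot be told apart from age.

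**Figure D2:**
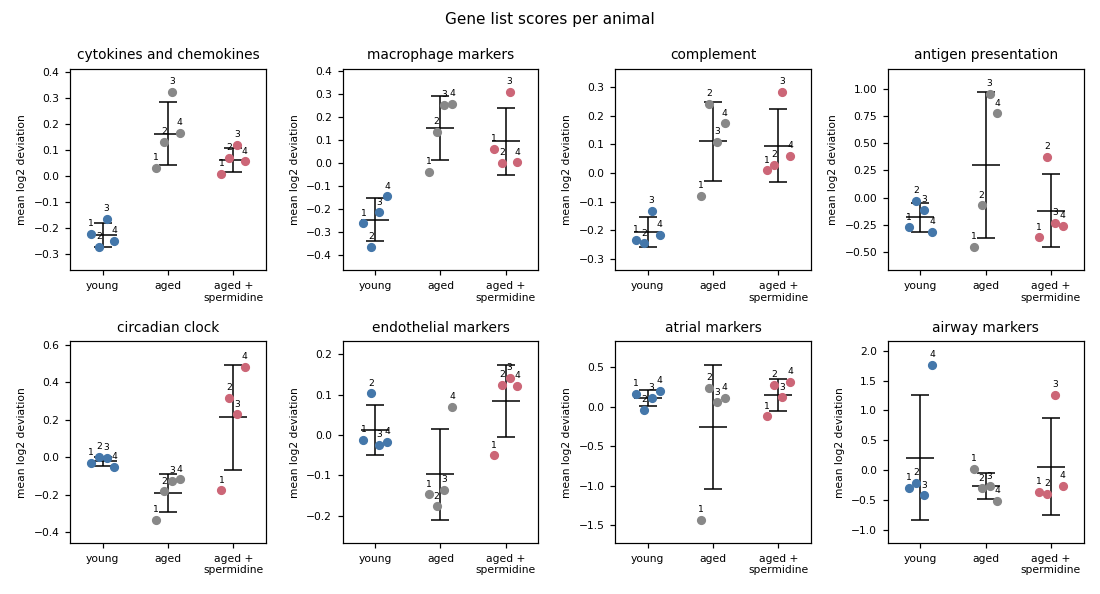
Score of 8 gene lists (y axis, mean log2 deviation of the members from their mean over the 12 arrays) by group (x axis). Each point is 1 animal, numbered by replicate, the long dash is the group mean and the bars span 1 SD either side (n = 4). The antigen presentation score is 0.95 in aged replicate 3 and 0.77 in aged replicate 4, and the atrial score is -1.43 in aged replicate 1.

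The lists for the contractile apparatus, energy supply, polyamines and autophagy did not pass in aged against young hearts. Median log2 differences were -0.01 for the sarcomere, -0.03 for respiratory complex I, -0.07 for fatty acid oxidation, 0.02 for polyamine metabolism, -0.03 for autophagy and 0.02 for mitophagy. Nppa, the atrial natriuretic peptide, differed by -0.35 (adjusted p = 0.58; 0.02 without aged replicate 1), Nppb by -0.09 (adjusted p = 0.89; 0.04 without aged replicate 3), and the cardiac myosins Myh6 by 0.03 and Myh7 by 0.13. Myh6 differed by -0.01 without aged replicate 2 or 3, and Myh7 by -0.37 without aged replicate 3 and -0.09 without young replicate 4. The collagen Col1a1 differed by -0.48 (adjusted p = 0.196), the protease inhibitor Timp1 by 0.84 (adjusted p = 0.0862), the cell cycle inhibitor Cdkn1a by 0.66 (adjusted p = 0.261), and the autophagy receptor Sqstm1 by 0.48 (adjusted p = 0.0889). Il6, Tnf and Cdkn2a stood below the background limit on all arrays.

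Hearts also differed in transcripts of other tissues, and these differences did not follow the groups. Airway transcripts stood high in young replicate 4 and spermidine replicate 3: the secretoglobin Scgb1a1 was at 12.89 and 11.47 in these, and Bpifa1 at 11.25 and 9.05, against 3.42 to 4.56 for Scgb1a1 elsewhere. The same arrays had adipocyte scores of 1.44 and 0.69, and young replicate 4 had a T cell score of 0.86. Aged replicate 1 was low in atrial transcripts, with Sln at 9.75 against 12.99 to 13.36 in the other aged hearts. Without the 2 arrays with airway transcripts, a setting added after seeing the data, 70 probes passed in aged against young hearts, and without the 3 arrays of unlike make-up 50.

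Between spermidine-treated and aged hearts 1 probe passed, that of Tmprss4, a membrane-bound serine protease. It stood at 3.83 ± 0.14 with spermidine and 5.49 ± 0.31 without (SD, n = 4 each), a difference of -1.65 (SE 0.20, adjusted p = 0.0218), at least 1.45-fold lower, since it lay below the background limit on all 4 treated arrays. Its other 2 probes, at -1.25 and 0.08, did not pass. The call was lost without aged replicate 1 (adjusted p = 0.0748), aged replicate 3 (0.0716), spermidine replicate 2 (0.067) or spermidine replicate 3 (0.0721). The next genes, not past the threshold (adjusted p = 0.355 each), were Slc25a47 (0.63) and Slco2a1 (0.52) on the higher side, and Hdhd3 (-0.90) and the interferon-induced kinase Eif2ak2 (-0.80) on the lower. Aqr, Ppp1r3b and Gnl2 lay below the background limit on all 4 aged arrays and were at least 1.42-, 1.21- and 1.34-fold higher with spermidine. Cwc22 lay below it on all 4 treated arrays and was at least 1.60-fold lower, and Fhl3, below it on all 4 treated and 2 of the aged arrays, allows no fold.

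The number of probes past the threshold with spermidine varied with single arrays. It was 49 without aged replicate 4 (9 higher and 40 lower), 3 without aged replicate 2, 5 without spermidine replicate 1, 5 without spermidine replicate 4, and 0 in limma without aged replicate 1, aged replicate 3, spermidine replicate 2 or spermidine replicate 3, where 1971, 1587, 1721 and 1540 probes had an unadjusted p below 0.05. In limma 1945 probes had an unadjusted p below 0.05 with spermidine, against 1029 expected on average by chance. Probes are not independent, and the spread of this count with no effect was not computed. The excess is therefore no sign of a spermidine effect by itself.

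Of the 40 lists, 6 passed with spermidine, 4 upward and 2 downward, and 0 members of them passed in limma over all probes. At least as many lists passed in 18 of the 35 splits of these arrays, so chance is not excluded for this count. Members at an unadjusted p below 0.05 numbered 3 for antigen presentation, 8 for interferon, 12 for the clock, 3 for endothelium, 0 for the atrium and 8 for the cytosolic ribosome. With an estimated correlation 0 lists passed, as with fry; unadjusted, 9 had a p below 0.05 in camera, 2 with an estimated correlation and 3 in fry. The count was 2 without aged replicate 4 and 3 without spermidine replicate 4. Antigen presentation genes were lower in 20 of 21 (median -0.39, adjusted p = 8.14e-05; adjusted p = 0.977 with an estimated correlation), with 0 adjusted over the list alone. Tap1 differed by -1.11 and Nlrc5 by -0.99 (-0.63 without aged replicate 4). The call was lost without aged replicate 3 (median -0.15, adjusted p = 0.0784) and aged replicate 4 (0.0581), the 2 aged hearts with high scores, the median was -0.67 without aged replicate 1 and -0.59 without spermidine replicate 2, and the score of the list differed with an exact p of 0.286. Interferon-stimulated genes were lower in 26 of 38 (median -0.15, adjusted p = 0.0358; adjusted p = 0.977 with an estimated correlation), with 0 adjusted over the list alone. Gbp2, a guanylate-binding protein, differed by -1.08. Without aged replicate 4 their median was 0.03 (adjusted p = 0.995), without aged replicates 1 and 2 it was -0.25 and -0.29, and the call was also lost without aged replicate 3 (0.234) and spermidine replicates 1 (0.331), 3 (0.0941) and 4 (0.0632).

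Clock genes were higher with spermidine in 13 of 18 (median 0.43, adjusted p = 0.0025; adjusted p = 0.428 with an estimated correlation), with 4 higher adjusted over the list alone: Dbp (1.40), Ciart (1.14, above the background limit on 2 of the aged arrays), Per2 (1.01) and Nr1d2 (0.95), output and repressor genes of the clock. Their score was -0.18 in spermidine replicate 1 and 0.32, 0.23 and 0.48 in replicates 2 to 4, against -0.34 to -0.12 in aged hearts (exact p = 0.0857). Endothelial markers were higher in 20 of 22 (median 0.16, adjusted p = 0.0025; adjusted p = 0.943 with an estimated correlation), with 0 adjusted over the list alone. The endothelial score was 0.07 in aged replicate 4 and -0.18 to -0.13 in the other aged hearts. It was -0.05 in spermidine replicate 1 and 0.12 to 0.14 in the other treated hearts (exact p = 0.0571). Vwf, the clotting factor made by endothelium, differed by 0.38 and the lipase anchor Gpihbp1 by 0.42. The clock and endothelial calls passed in all 12 fits that left out 1 array, with a clock median of 0.27 without spermidine replicate 4.

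Atrial markers were higher in 14 of 15 (median 0.43, adjusted p = 0.0468; adjusted p = 0.977 with an estimated correlation), with 0 adjusted over the list alone and Myl7, the atrial myosin light chain, at 1.11 (0.33 without aged replicate 1). Without aged replicate 1, whose score was -1.43, the median was -0.01 (adjusted p = 0.808), and the call was also lost without aged replicate 4 (0.0581), spermidine replicates 2 (0.189), 3 (0.0633) and 4 (0.155) and young replicates 1 (0.0504) and 3 (0.0527). Cytosolic ribosome genes were higher in 37 of 56 (median 0.06, adjusted p = 0.0317; adjusted p = 0.977 with an estimated correlation), with 0 adjusted over the list alone. The median was 0.10 without aged replicate 1 or spermidine replicate 1, and that call was lost without aged replicates 3 (0.0784) and 4 (0.458) and spermidine replicates 2 (0.189), 3 (0.0873) and 4 (0.0577).

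The lists for polyamine metabolism (median 0.05), autophagy (0.02), mitophagy (-0.03), respiratory complex I (0.02), fatty acid oxidation (-0.02) and the sarcomere (0.02) did not pass with spermidine. Odc1 and Srm, enzymes of polyamine synthesis, differed by 0.04 and 0.16, and Sat1, which starts polyamine breakdown, by -0.15. The autophagy genes Map1lc3b and Sqstm1 differed by 0.41 (adjusted p = 0.495) and -0.06 (adjusted p = 0.913; 0.02 without aged replicate 4), Nppa by 0.35 (adjusted p = 0.691; -0.01 without aged replicate 1) and Myh7 by 0.68 (adjusted p = 0.733; 0.28 without aged replicate 4 and 0.26 without spermidine replicate 4).

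The probes that passed with age mostly stood nearer to young in treated hearts. Of the 164, 144 (87.8%, exact 95% interval 81.8% to 92.4%, counting error only) had a spermidine mean on the young side of the aged mean, and the median share of the ageing difference returned was 38.1%. The aged arrays enter both comparisons, and simulated spermidine hearts drawn like aged hearts gave 66.9% on average and a share as high in 4 of 100 simulations. The count of probes past the threshold in treated against young hearts was 20.1% of that in aged against young hearts, a ratio as low in 1 of 100, though these simulations made 324 ageing calls on average against 164. With the aged arrays split into 2 pairs, 164 probes were ranked first on one pair, not the 164 above, and the share of these toward young on the other pair was 69.7% on average (59.8% to 79.9%) against 52.2% simulated with the ageing effect kept and spermidine hearts drawn like aged hearts, as high in 15 of 100. Across probes, which are not independent replicates, the differences with age and with spermidine correlated at r = -0.65, against -0.49 on average (-0.90 to 0.09) with no effect simulated and -0.37 (-0.78 to 0.11) with the ageing effect kept and spermidine hearts drawn like aged hearts. Their covariance was -0.0464 against a simulated -0.0205, as low in 6% of simulations, and with split aged arrays r was -0.21, as low in 21 of 100 with no effect and 23 of 100 with the ageing effect kept.

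**Figure D3:**
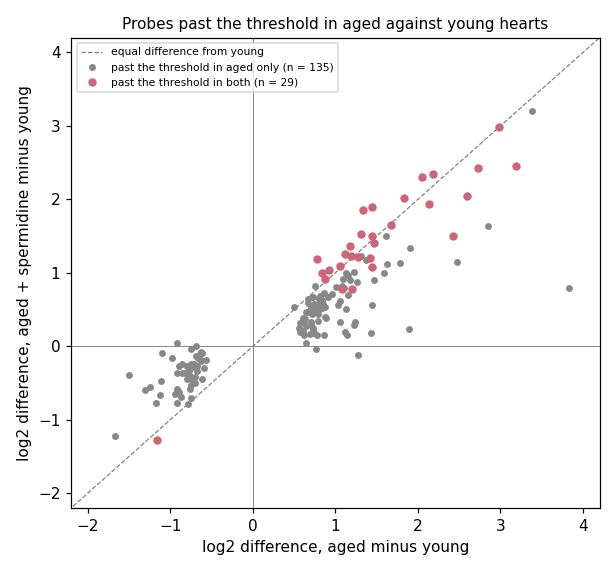
Log2 difference of spermidine-treated minus young hearts (y axis) against that of aged minus young hearts (x axis) for the 164 probes past the threshold with age. Red points (29) also passed in spermidine-treated against young hearts, grey points (135) did not, and the dashed line marks equal differences; 144 points lie on the young side of it.

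Against young hearts, spermidine-treated hearts differed in 33 probes, 31 higher and 2 lower, led by the genes that were also higher in untreated aged hearts. Klk1b26 rose 7.93-fold (7.92 ± 0.25 against 4.93 ± 0.24, SD, n = 4 each, adjusted p = 0.000564), Ccl8 5.49-fold (adjusted p = 0.0006), Kcnk1 5.37-fold (adjusted p = 0.00378) and Csprs 4.93-fold (adjusted p = 0.000564). Serpina3n, an acute-phase protease inhibitor, rose 3.60-fold (8.18 ± 0.41 against 6.33 ± 0.20, adjusted p = 0.0036). Cd209b, Serpina1d, Vgll2 and Prom2 rose at least 2.30-, 2.28-, 2.27- and 1.77-fold, and Sh3gl2 4.06-fold (adjusted p = 0.0243), with the other probes of Prom2 and Sh3gl2 at 0.06 to 0.39. Ddc fell by 1.28 (adjusted p = 0.0215), with 2 treated arrays above the background limit. Nle1 passed as lower (adjusted p = 0.0407) but lay below the limit in both groups, so no size is given.

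Of the 33 probes, 28 higher and 1 lower were also past the threshold in aged hearts, against 0.167 and 0.00515 for independent lists. The young arrays are shared, and simulations that kept the ageing effect and drew spermidine hearts like aged hearts gave 107 and 60.9 on average, from 324 and 375 calls, so the overlap is no sign of a separate spermidine effect. Simulations with no effect gave 0.01 and 0, from 9.75 ageing calls. The count was 19 without spermidine replicate 3, 18 without spermidine replicate 4, and 16, 20 and 17 without young replicates 1, 2 and 3. Without the 2 arrays with airway transcripts it was 12. Of the 12 named genes, 8 passed in all 12 fits that left out 1 array. Nle1, Sh3gl2, Ddc and Serpina1d did not. Without young replicates 1 and 3 all 4 were lost (adjusted p 0.0540 to 0.147 and 0.0509 to 0.176). Sh3gl2, Ddc and Nle1 were lost without young replicate 2 (0.0558 to 0.0873), spermidine replicate 3 (0.0856 to 0.174) and spermidine replicate 4 (0.0986 to 0.171). Nle1 was also lost without young replicate 4 (0.0626) and aged replicate 1 (0.0528), and Sh3gl2 without spermidine replicate 1 (0.0522).

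Of the 40 lists, 5 passed in spermidine-treated against young hearts, 4 upward and 1 downward, and 10 without spermidine replicate 1. At least 5 lists passed in 14 of the 35 splits of these arrays, so chance is not excluded for this count. Macrophage markers were higher in 21 of 25 (median 0.42, 0.28 without spermidine replicate 3, adjusted p = 3.06e-09; adjusted p = 0.0769 with an estimated correlation), with 0 past in limma over all probes, 10 adjusted over the list alone and 12 at an unadjusted p below 0.05. Cytokines and chemokines were higher in 32 of 45 (median 0.17, adjusted p = 0.00012; adjusted p = 0.0172 with an estimated correlation), with Ccl8 past over all probes and 8 adjusted over the list alone. Complement genes were higher in 13 of 15 (median 0.19, 0.29 without spermidine replicate 1, adjusted p = 0.00012; adjusted p = 0.0769 with an estimated correlation), with C4b past over all probes (1.36, adjusted p = 0.0407) and 3 adjusted over the list alone. The call of C4b was lost without young replicates 1 (adjusted p = 0.149), 2 (0.114), 3 (0.156) and 4 (0.0670), spermidine replicates 2 (0.0632), 3 (0.171) and 4 (0.171), and aged replicate 3 (0.0519). Genes of the oxidative stress response were higher in 24 of 34 (median 0.08, adjusted p = 0.00405; adjusted p = 0.599 with an estimated correlation), with 0 past in limma over all probes, 5 at an unadjusted p below 0.05 and 3 adjusted over the list alone: Gsta1 (1.11), Nqo1 (0.52) and Gsta4 (0.44), enzymes of detoxification. The median of the list was 0.14 without spermidine replicate 1, 0.05 without spermidine replicate 3 and 0.12 without young replicate 4. Smooth muscle and pericyte markers were lower in 15 of 17 (median -0.11, adjusted p = 0.0137; adjusted p = 0.848 with an estimated correlation), with 0 past in limma over all probes, 0 adjusted over the list alone and 2 at an unadjusted p below 0.05, and the call was lost without spermidine replicate 4 (0.0885) and young replicate 2 (0.256), with a median of -0.22 without spermidine replicate 1.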

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

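The tests of antigen presentation scores per animal, of the phase score of spermidine replicate 1 and of exchanged labels were chosen only after the results were seen.

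Within groups of 4 animals, 471 sets of values of 117 genes and 40 lists were searched for 1 animal far from the other 3, by the gap to the nearest animal over the range of the group at Dixon's 95% limit. Past it were 40, of which 25 were of genes and 15 of lists. Chance flags about 1 in 20 groups, which gives 23.55 here.

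Atrial transcripts were low in aged replicate 1. Myl7 stood at 8.77 against 11.88 to 11.93 in the other aged hearts (ratio 0.985), Sln at 9.75 against 12.99 to 13.36 (0.898), the natriuretic peptide Nppa at 12.99 against 14.42 to 14.46 (0.973), and the score of the atrial list had a ratio of 0.890. The same heart was low in the complement gene C4b (0.874) and the erythroid list (0.879) and high in the mitochondrial ribosome list (0.896). Airway transcripts were high in young replicate 4 (list score 1.77, ratio 0.903) and spermidine replicate 3 (1.27, ratio 0.919). Young replicate 4 was also high in T cell markers (0.882) and the oxidative stress list (0.885) and low in Tnf (0.867), which lay below the background limit. Spermidine replicate 3 was high in B and plasma cell markers (0.863) and the cell cycle inhibitor Cdkn1a (0.857), and low in calcium and ion handling (0.920).

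Spermidine replicate 2 was high in interferon-inducible GTPases, with Irgm2 at 10.83 against 9.01 to 9.15 (0.922) and Gbp3 at 9.57 against 7.93 to 8.19 (0.839), in the class I activator Nlrc5 (0.839) and in the interferon list (0.847). Spermidine replicate 1 stood low in the clock repressor Per2, at 7.05 against 8.43 to 8.55 (0.919), in endothelial markers (0.90) and in the ribosomal gene Rps10 (0.869), and high in the collagen Col3a1 (0.906). Spermidine replicate 4 was high in Cap1, at 7.55 against 3.89 to 4.09 (0.947), and in Ppp1r3b (0.872), and low in Spata7 (0.888) and the natriuretic peptide Nppb (0.865). Aged replicate 4 was high in Cpt1b, which carries fatty acids into mitochondria (0.857), in Rps10 (0.881), Eps8l1 (0.832) and endothelial markers (0.833). Aged replicate 3 was high in Oas1g (0.849) and Tnf (0.834) and low in the extracellular matrix list (0.938), and aged replicate 2 was high in Dusp1 (0.833). Young replicate 2 was high in the immunoproteasome subunit Psmb8 (0.862) and endothelial markers (0.903), and low in the autophagy gene Map1lc3b (0.973) and the cytosolic ribosome list (0.846), and young replicate 3 was high in Ccl8 (0.833).

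Antigen presentation genes were lower with spermidine as a list, and the aged animals differed among themselves. Of the 4 aged hearts, 2 scored above every spermidine heart (0.95 and 0.77), those numbered 65 and 66 in the titles. The other 2, numbered 5 and 4, lay at -0.07 and -0.45, on either side of the spermidine mean of -0.12. High and low scores thus went with neighbouring numbers, a relation that was not tested. The score of -0.45 also lay below the young mean of -0.18, which goes against a shift of all 4 but is 1 heart. Whether some aged animals stood in a high state or all 4 were shifted stays open, since the count of 2 restates scores already seen and its bar was set by 1 spermidine heart at 0.38. Fewer leukocytes in treated hearts stay open too: the antigen presentation score differed by -0.36 more than the macrophage score, and an exact permutation test gave p = 0.229. The call was lost without aged replicate 3 (median -0.15, adjusted p = 0.0784) and without aged replicate 4 (0.0581), and an effect of spermidine is also open.

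Clock genes were higher with spermidine as a list, and the medians of its phases lay on opposite sides of 0. Day-peaking genes had a median log2 difference of 0.95 (9 genes, with Hlf at 0.06, SE 0.15) and genes of the opposite phase one of -0.47 (4 genes, with Clock at -0.02, SE 0.15), and 0 of the 13 passed in limma over all probes (9 at an unadjusted p below 0.05), which is consistent with collection at another time of day, a time not given in the sources used here. The phase score of spermidine replicate 1 was -0.46, inside the aged range of -0.95 to -0.07, against 1.31, 0.85 and 1.20 in replicates 2, 3 and 4 (exact p = 0.0857 between the groups), so an effect shared by all 4 treated animals is not shown. Animals with neighbouring numbers in the titles had like scores, at -0.91 and -0.95 for aged animals 4 and 5, -0.07 and -0.08 for aged animals 65 and 66, and 0.85 to 1.31 for spermidine animals 75 to 77. Young animals 49 to 52 scored -0.31 to -0.12. Spermidine replicate 1, at -0.46, was animal 36 and so stood apart in number from the other treated animals. This relation was not tested. Time of collection and treatment cannot be told apart here, because the time of each animal is not known.

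Aged replicate 4 stood with the treated hearts, and spermidine replicate 1 lay between the groups, on a first principal component (26.9% of variance) at 2.11 and -4.27, against 4.88 to 5.67 in the other treated and -24.93 to -14.63 in the other aged hearts. In spermidine-treated against aged hearts 6 of the 35 splits of the 8 arrays gave at least the 1 probe of the real split, so chance is not excluded, and the highest other split called 387, which points to a structure of the samples: it set spermidine replicate 1 with aged replicates 1 to 3. On an axis from the aged mean (0) to the spermidine mean (1), made without the animal placed, aged replicate 4 lay at 0.75 and spermidine replicate 1 at 0.46, each past the midpoint of 0.5 toward the other group on 4 of 4 axes, and aged replicate 1, at 0.49 on average, was past it on 3 of its 4 axes. Exchanged labels stay open: the axis was drawn after that split was seen and on the same arrays, so it adds no support. Scores per animal went both ways. Aged replicate 4 scored above every treated heart in antigen presentation, and its phase score of -0.08 lay below those of treated replicates 2 to 4. Spermidine replicate 1 had a phase score of -0.46, inside the aged range. A source of difference unrelated to treatment stays open too, since young hearts lay at 0.70 to 0.85 with a spread of 0.152, and no animal was moved to another group.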

How the results depend on the processing

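The background-limit filter, the offset of 64 and the settings without the 2 arrays with airway transcripts or the 3 arrays of unlike make-up were tests chosen only after the data were seen. Signal over background limits these results: 45.5% to 48.0% of the probes of an array stood above the limit, and dim probes have understated differences. Slide as a block was not run, as no slide was given in the sources used here. Quantile normalization of the log2 signal and median scaling moved no count of probes by over 1.5 times. The cause was not tested for any change below, except that settings with fewer arrays or probes differ by construction.

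In aged against young hearts the count of 164 probes became 299 with the submitters' values, 90 with no filter, 298 with probes detected on all 12 arrays, 337 with trend and robust eBayes, 372 with array weights, 97 with only the 8 arrays compared, 106 with probe means and 33 with a gene-wise Student test. It was 331 with the background-limit filter, 373 with offset 64, 70 without the 2 airway arrays and 50 without the 3 arrays. The count of 33 in spermidine-treated against young hearts became 52 with trend and robust eBayes, 105 with array weights, 51 with only 8 arrays, 5 with the Student test, 12 without the 2 airway arrays and 16 without the 3. The single call between spermidine-treated and aged hearts, Tmprss4, was lost, leaving 0 in limma, with probes detected on all 12 arrays (1669 at an unadjusted p below 0.05), probe means (1174) and offset 64 (2126), and 0 in the Student test (1365). Its adjusted p was 0.203 with probe means, 0.741 in the Student test and 0.0627 with offset 64.

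Lists past the threshold numbered 1, 0 and 1 with an estimated correlation and 3, 0 and 3 with fry, for aged against young, spermidine-treated against aged and spermidine-treated against young hearts. In aged against young hearts 13 lists passed without the 3 arrays and 3 scores per animal differed without the 2 airway arrays, against 8 and 5. Adipocyte markers turned from a median of -0.07 to 0.31 (adjusted p = 0.00204) without the 3 arrays in aged against young hearts. With spermidine against aged hearts, the atrial median turned from 0.43 to 0.0077 (adjusted p = 0.952) without the 3 arrays.

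Leaving out 1 array at a time gave 41 to 559 probes in aged against young, 0 to 49 in spermidine-treated against aged and 16 to 48 in spermidine-treated against young hearts (48 without aged replicate 4). Lists ran from 6 to 10, 2 to 7 and 4 to 10. In spermidine-treated against aged hearts 2 lists passed without aged replicate 4 and 3 without spermidine replicate 4, and in spermidine-treated against young hearts 10 without spermidine replicate 1. Scores per animal past an exact p of 0.05 ran from 1 to 7, 0 to 4 and 3 to 6. Those of aged against young hearts were 3, 2, 1 and 3 without young replicates 1 to 4. Those of spermidine-treated against aged hearts were 4 without aged replicate 1, 3 without aged replicate 4 and 1 without spermidine replicate 1. Those of spermidine-treated against young hearts were 5, 5 and 6 without young replicates 1, 2 and 4, and 5 without spermidine replicate 1. The share of ageing calls on the young side ran from 78.0% to 97.0%, and the correlation of differences from -0.73 to -0.60. With spermidine against aged hearts the interferon median ran from -0.29 to 0.03 (0.034 without aged replicate 4) and the atrial median from -0.01 to 0.62 (-0.012 without aged replicate 1).

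No pairing of the animals by replicate number was seen, but the check cannot exclude one. Deviations can be alike without a shared number, as spermidine replicate 3 and a young array of another number correlated at 0.50. Of 12 pairs with the same number, 4 had deviations that correlated above 0.1 (r from -0.33 to 0.20), and 3 matched their own number best. With the replicate block, 96, 0 (2006 at an unadjusted p below 0.05) and 30 probes and 8, 4 and 5 lists passed in the order above, and Tmprss4 had an adjusted p of 0.209. Over all settings, named genes past the threshold kept direction and call in 964 cases and lost the call with the same direction in 376, and lists did so in 455 and 74. Lists past the threshold turned direction in 3 cases, the interferon and atrial ones above, and another list in 1, that of adipocyte markers.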

Other observations

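The tests of the return of ageing calls toward young were chosen only after the result was seen, and the genes of the next paragraph are list members named after their values were seen.

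Single genes passed in aged against young hearts in lists that did not pass as a whole. Psmb5, a catalytic subunit of the proteasome, fell by 0.92 on the log2 scale (adjusted p = 0.0255), and the clock repressor Nr1d1 fell by 0.85 (0.0446). Other day-peaking clock genes went both ways, with Dbp at -0.70, Nr1d2 at -0.69 and Tef at -0.49 but Per2 at 0.22 and Hlf at 0.19. The phase score of aged against young hearts had an exact permutation p of 0.429. Time of collection was not given, so for Nr1d1 it cannot be told apart from age. Fmod, a proteoglycan that binds collagen, fell by 0.74 (0.0398), the water channel Aqp1 of endothelium fell by 0.73 (0.0381), the replication helicase subunit Mcm6 fell by 0.70 (0.0478), and Atp5g2, which encodes a subunit of the mitochondrial ATP synthase, fell by 0.60 (0.0317). The myosin light chain Myl1 rose by 0.92 (0.0260), the mitochondrial ribosome gene Mrps10 by 0.79 (0.0330) and the quinone reductase Nqo1 by 0.76 (0.0217). All 9 calls were lost without aged replicate 2 (adjusted p 0.0531 to 0.122) and without young replicates 1 (0.0838 to 0.148), 2 (0.0627 to 0.124) and 3 (0.0705 to 0.145), and 6 without young replicate 4 (0.0579 to 0.118). Without aged replicates 1 and 3, 4 (0.0552 to 0.108) and 6 (0.0557 to 0.0877) were lost, and without spermidine replicates 1 to 4 it was 2 (0.0544 to 0.0616), 3 (0.0524 to 0.0573), 4 (0.0546 to 0.0638) and 4 (0.0516 to 0.0615).

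The other lists did not pass in aged against young hearts. Their median log2 differences were -0.05 for respiratory complexes II to IV, -0.08 for complex V, 0.01 for the citric acid cycle, 0.05 for the mitochondrial ribosome, -0.03 for glycolysis and glucose uptake, -0.08 for the hypertrophy program, -0.12 for calcium and ion handling and -0.12 for the extracellular matrix. Among stress and turnover lists they were 0.02 for senescence and p53, -0.03 for the lysosome, -0.11 for heat shock chaperones, -0.05 for the unfolded protein response, 0.07 for the oxidative stress response, 0.02 for the proteasome, -0.15 for the clock and -0.10 for the cell cycle. Among markers of cell types they were 0.05 for T cells, 0.20 for B and plasma cells, -0.36 for the atrium (-0.05 without aged replicate 1, and an adjusted p of 0.0253 without aged replicate 2), -0.06 for endothelium, -0.06 for fibroblasts, -0.07 for adipocytes, 0.07 for skeletal muscle, 0.23 for erythroid cells, -0.11 for airways and -0.20 for mesothelium and Schwann cells. The mean had the other sign than the median for the citric acid cycle, glycolysis, the sarcomere, T cells, polyamine metabolism and the proteasome. Xist, an X-linked transcript, stood at 5.82 to 6.50 on its brighter probe, Kdm5d and Eif2s3y of the Y chromosome lay below the background limit on all 12 arrays, and Uty, also of the Y chromosome, lay above it on 6. Uty stood at 4.44 to 5.11 over the arrays, near the lowest signal above the limit on an array (4.89 to 5.03), so no sex is read from it.

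Other splits of the same arrays were counted for each comparison. For aged against young hearts the real split, with 164 probes, was 1 of 35 to give as many, and the highest other gave 0. For spermidine-treated against young hearts the real split, with 33 probes, was 1 of 35, and the highest other gave 4. Both met the bar against chance that was set beforehand. As 1 of 35 is the smallest share the splits can give, they cannot exclude chance. They also cannot tell age or treatment from other differences between the groups. For lists the bar was not met in any comparison, and chance is not excluded. Of 35 splits, 15 gave as many lists as the 8 of aged against young hearts (highest other 14), 18 as many as the 6 of spermidine-treated against aged hearts (highest other 9), and 14 as many as the 5 of spermidine-treated against young hearts (highest other 11).

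A hypothesis was that ageing calls lie toward young in treated hearts only through chance in the shared aged arrays. With split aged arrays, 15 of 100 simulations that kept the ageing effect and drew spermidine hearts like aged hearts gave a share of ranked probes toward young as high as the observed one. With all aged arrays, 4 of 100 gave as high a share of ageing calls toward young, 7 as high a share returned, and 1 as low a ratio of calls in treated to calls in untreated aged hearts (20.1% observed). These values point different ways, and the simulations made 324 ageing calls on average against 164, so chance is neither shown nor excluded. A second hypothesis was a difference in C57BL/6 substrain between young and aged mice, which could give large differences in single genes. Nnt, disrupted in one substrain, differed by -0.32 on its brightest probe, but all 3 Nnt probes lay below the background limit on all 12 arrays, so a bound of less than 1 on the log2 scale, set as evidence against the hypothesis, was void. Of the other genes chosen for this check, Entpd4 lay above the limit on all 12 arrays and differed by 0.025, which argues against a difference as far as its probe follows substrain, and Wdfy1, above the limit on 1 array, differed by 0.69. The hypothesis stays open, since no size was set for these genes beforehand.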
